A study of Mus musculus with 12 samples.

How the data were processed

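Hearts of male C57BL/6J mice were profiled by RNA sequencing in 4 groups of 3 libraries: untrained control mice, trained mice, untrained mice given melanoma cells (tumour), and trained mice given melanoma cells (tumour trained). Groups and replicate numbers were read from the sample titles. Per the labels' protocols, RNA was purified with Trizol and libraries were made with a Vazyme VAHTS Universal V8 kit for MGI sequencers. The same protocol names livers as the source of the RNA, whereas the tissue label says heart. The liver gene Alb was at most 3.93 CPM (counts scaled to the size of the library) in any library and the cardiac gene Myh6 was the most abundant gene in 11 of the 12.

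The values used are estimated counts per gene, deposited as 1 table for the whole series and not normalized. Per the submitters' processing notes, HISAT2 2.2.1 and featureCounts were used, and the builds GRCm39 and mm10 are both named. Which build gave the table, the annotation, the strand setting and any filter on genes are not given in the sources used here, so no coordinates are printed. Overlapping and antisense genes cannot be told apart without the strand setting. Between 7.09% and 8.92% of the values in a library were not whole numbers, which plain counting of reads would not give. How reads shared between genes were divided is not stated, so near-identical paralogs such as the haemoglobin genes are uncertain. The table held 17397 genes by gene ID and symbol, of which 17288 IDs were found in a mouse RefSeq gene table. It held no mitochondrially encoded gene. A total of 24 symbols had been turned into dates in the deposited table and were restored from the gene ID.

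Estimated counts were rounded to whole numbers. Library totals ranged from 8843906 to 13344847 counts, so that 3 counts correspond to 0.225 to 0.339 CPM. Levels are given as CPM scaled with the trimmed mean of M values (TMM), as mean ± SD over 3 libraries. Shares of counts use the plain library total, with 95% Wilson intervals. Intervals and the floor of 3 counts cover counting error only. Replicates of a group were compared by chi-square over genes. Every pair differed by more than sampling noise, from 3.81 per gene (tumour trained 1 and 3) to 387.63 per gene (tumour 1 and 3), and none was merged.

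Genes were tested with edgeR 4.0.16 in R 4.3.3, in 1 quasi-likelihood fit of the 12 libraries with 1 mean per group and 8 residual degrees of freedom. The default filter on low counts by group left 12778 genes and removed 4619. The 5 contrasts read from this fit were tumour against control, tumour trained against tumour, trained against control, tumour trained against trained, and the interaction of tumour and training. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, among 49 lists (29 pathway, 20 cell type) of which 42 had at least 5 tested members, and adjusted over the lists of a comparison. With an estimated correlation, no list call of the fit of 12 libraries held.

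The genes named were set by a rule before the data were examined: a panel of 34 genes in the 2 comparisons that involve the untrained tumour group, whatever their result. To these were added up to 10 higher and 10 lower genes per comparison by size of change, among called genes with a mean log2 CPM of at least 1 and, except in the interaction, no overlap between the libraries of the groups. Up to 4 members of each list by p were also taken, and Sox10, Pmel, Tyrp1, Dct, Mlana and Alb served as a check for other tissue. Genes with provisional symbols were left out of the ranking by size. Some genes that met the rule are not reported here.

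The scripts were tested on simulated counts with 50 genes changed at each fold. With the spread of the 12 libraries, the tumour comparison recovered 24% of genes changed 2-fold and 92% of those changed 4-fold, and the training comparison in tumour-free mice 18% and 74%. A list raised in simulated counts was recovered with the preset and with the estimated correlation (adjusted p = 4.35e-07 and 0.028), with no other list called. Genes were simulated independently, so this does not test either setting on lists whose members vary together. With the spread of the 10 libraries left without tumour 1 and 2, the shares of genes recovered were 86% and 100%, and 74% and 100%. Those runs still held 3 tumour libraries, so they do not give the recovery of the fit with tumour 3 alone. Alternatives set before the data were examined were DESeq2 1.42.0, its size factors within edgeR, library size alone, no filter or a stricter filter on low counts, robust dispersion, the replicate number as a block, a fit of only the 2 groups compared, a minimum log2 change of 1, an estimated correlation for lists, and leaving out each library. After the data were seen, fits without tumour 1 and 2, without these and trained 2, with a correction for transcript GC content (with and without those libraries), and with scaling to cardiomyocyte genes were added. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.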

Results

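Heart RNA was measured in 8-week-old male C57BL/6J mice to ask how low-intensity treadmill training and metastatic melanoma, alone and together, alter the heart. Trained mice ran on 5 days a week for 4 weeks. After 1 adaptation week at 6 to 15 m/min, each session was 5 min at 6 m/min and 35 min at 12 m/min. Tumour groups received 100000 B16F10 cells, a mouse melanoma line, through the tail vein from week 2. Control mice were labelled saline; whether trained mice also received saline is not stated. Control, trained, tumour and tumour trained groups had 3 libraries each. Total counts were 10817479, 10687870 and 10086008 in control 1, 2 and 3, and 8843906, 11932234 and 9564691 in trained 1, 2 and 3. They were 13344847, 12974833 and 11447644 in tumour 1, 2 and 3, and 9627484, 9504109 and 9773016 in tumour trained 1, 2 and 3. Levels are given as CPM, counts scaled to the size of the library. The labels do not say that each library is from a separate mouse, so p-values measure only the spread between these samples.

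Melanoma transcripts were abundant in 2 of the 3 hearts of untrained tumour-bearing mice. Sox10, Pmel, Tyrp1, Dct and Mlana, genes of the melanocyte lineage and its pigment synthesis, together held 1.08% of the counts of tumour 1 (95% Wilson interval for counting error only, 1.076 to 1.087) and 0.496% of those of tumour 2 (0.4924 to 0.5001). In tumour 3 they held 0.00166% (0.00144 to 0.00191), against at most 0.00104% (8.69e-04 to 0.00126) in the 9 libraries of the other groups. Tyrp1 had 61345, 21693 and 15 counts in tumour 1, 2 and 3 and 0 counts in those 9 libraries, where 3 counts would be 0.251 to 0.339 CPM without TMM scaling. Without that scaling, its log2 difference between the tumour mean and the other groups was at least 12.6 with 3 counts per library in place of 0. Cardiomyocyte genes moved the other way. Their list held 3.81% of counts in tumour 1 (3.80 to 3.82), 9.40% in tumour 2 (9.38 to 9.42) and 14.9% in tumour 3 (14.85 to 14.89), against 14.6% to 15.9% in the other groups. Myh6, the main myosin heavy chain of the adult mouse heart, was at 6525, 17896 and 35944 CPM in tumour 1, 2 and 3 and at 35921 ± 1877.5 CPM in control hearts (SD, n = 3).

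**Figure D1:**
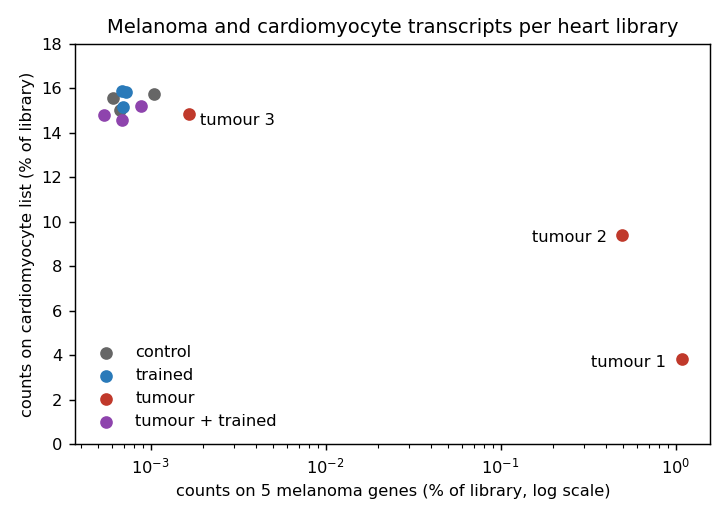
Share of counts on 5 melanoma genes (horizontal axis, % of library, log scale) against the share on the cardiomyocyte list (vertical axis, % of library), with 1 point per library coloured by group. Tumour 1 (1.08% and 3.81%) and tumour 2 (0.496% and 9.40%) lie apart from tumour 3 and the 9 libraries of the other groups.

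In untrained mice, tumour-bearing hearts had far higher levels of a small set of stress and acute phase genes than control hearts, in all 3 libraries including tumour 3. Hmox1 (gene ID 15368), which encodes the haem-degrading enzyme haem oxygenase 1, rose from 14.1 ± 1.45 CPM to 172 ± 57.5 CPM (SD, n = 3), a log2 fold change of 3.61 ± 0.23 (SE, edgeR adjusted p = 3.24e-05). Mt2 (gene ID 17750), a metal-binding metallothionein, rose from 15.5 ± 0.884 to 236 ± 15.8 CPM (log2 3.93 ± 0.18, adjusted p = 1.50e-06). Fkbp5 (gene ID 14229), a glucocorticoid-induced co-chaperone of the glucocorticoid receptor, rose from 17.6 ± 0.726 to 81.6 ± 10.1 CPM (log2 2.21 ± 0.19, adjusted p = 4.97e-04). The acute phase genes Serpina3n (12.5 ± 0.328 to 175 ± 107 CPM, log2 3.81 ± 0.36, adjusted p = 9.06e-04) and Lcn2 (2.40 ± 0.683 to 30.7 ± 19.6 CPM, log2 3.68 ± 0.47, adjusted p = 0.015) rose as well.

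Mt1, another metallothionein, rose from 182 ± 15.3 to 572 ± 193 CPM (adjusted p = 0.015). Higher too were Gclm, a subunit of the glutathione-synthesis enzyme (24.0 ± 1.29 to 42.3 ± 8.65 CPM, adjusted p = 0.039), and 2 genes of lipid use. These were Angptl4, a secreted inhibitor of lipoprotein lipase (10.8 ± 3.73 to 58.7 ± 17.5 CPM, adjusted p = 0.039), and the lipid droplet gene Plin2 (60.7 ± 1.33 to 118 ± 13.4 CPM, adjusted p = 0.0283). The oxidative stress list had 6 of 28 members higher and none lower over all genes tested, and 12 higher adjusted over the list alone (camera adjusted p = 2.71e-04; adjusted p = 0.649 with an estimated correlation). The glucocorticoid response list had 6 of 24 members higher and 2 lower, and 10 and 4 adjusted over the list alone (camera adjusted p = 7.29e-04, and adjusted p = 0.649 with an estimated correlation). The median log2 ratio to control of the oxidative stress list was -0.298, 0.3155 and 0.371 in tumour 1, 2 and 3. That of the glucocorticoid list was -0.124, 0.325 and 0.730, so neither median was raised in tumour 1.

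In all, edgeR called 868 genes between tumour and control hearts, 681 higher and 187 lower. The median log2 difference to control of the 681 was 2.32 in tumour 1 and 2 and 0.324 in tumour 3. In tumour 3, which entered the calls, 438 of the 681 (64.3%) were above all 3 controls, against 31.9% of all genes tested. Of the 187 lower genes, 184 (98.4%) were below all 3 controls in tumour 3. The share of all genes tested below the controls was not taken. The median log2 difference of the 187 was -1.41 in tumour 1 and 2 and -0.928 in tumour 3. Pmel (log2 12.08 ± 2.05), Gpnmb (8.90 ± 1.62), Dct (8.03 ± 1.44) and Sox10 (6.11 ± 1.15) were among the highest, with 5 of 7 melanocyte genes higher and 6 adjusted over the list alone. This list's median log2 change was 8.03, with Tyrp1 as fitted or at its bound from 3 counts per library, and its adjusted p was 1.49e-04 (0.649 as an adjusted p with an estimated correlation). Of 31 cell cycle genes 28 were higher (30 adjusted over the list alone), among them Cdk1 and Plk1 (median log2 4.15, adjusted p = 1.13e-14; adjusted p = 0.649 with an estimated correlation). In the fit without tumour 1 and 2 the cell cycle list had a median of 0.04 and no called gene (adjusted p = 0.935). Mki67, a proliferation marker chosen after its values were seen, was at 184, 34.0 and 1.20 CPM in tumour 1, 2 and 3, against 0.487 to 1.34 CPM in control hearts.

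Genes lower in all 3 tumour libraries than in any control included Itgb6, an integrin subunit (16.7 ± 2.39 to 3.64 ± 2.82 CPM, log2 -2.20 ± 0.51, adjusted p = 0.0401), and the slow-type myosin Myh7b (59.1 ± 13.6 to 14.3 ± 9.50 CPM, log2 -2.06 ± 0.39, adjusted p = 0.039). In the fit without tumour 1 and 2 these were -2.09 and -1.26 (adjusted p = 0.00511 and 0.0254). Bcl6b, Ces2e, Lrrc4b, Ky, Grhl2, Retnla and Pla2g2d were lower by 2.04 to 2.48 on the log2 scale. The vascular growth factors Apln (log2 -1.32 ± 0.20, adjusted p = 0.0323) and Vegfa (log2 -1.23 ± 0.22, adjusted p = 0.039) were lower. Scaled to cardiomyocyte genes, which moved the median of all genes to 1.52, their log2 changes were 0.253 and 0.007. Neither therefore fell more than cardiomyocyte genes as a whole. Lists of heart muscle function had lower medians with the libraries' melanoma content: oxidative phosphorylation (77 genes, median log2 -0.67, adjusted p = 7.87e-18), the TCA cycle (24 genes, -0.59), the sarcomere (26 genes, -0.66), potassium and sodium channels (24 genes, -0.69) and calcium handling (20 genes, -0.52). Each had an adjusted p = 0.649 with an estimated correlation, and together they held 1 lower and 2 higher called genes. Their medians without tumour 1 and 2 were 0.01, 0.08, -0.03, -0.08 and -0.09.

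Of the panel of 34 genes, 31 were tested and 9 were called, all higher. The fetal myosin gene Myh7 was 1 of them (log2 2.12 ± 0.56, adjusted p = 0.0479), with 379, 1278 and 174 CPM in tumour 1, 2 and 3 and 140 ± 38.2 CPM in control hearts; without tumour 1 and 2 its log2 change was 0.32 (adjusted p = 0.751). The 22 tested genes that did not pass included the natriuretic peptides Nppa (log2 0.41 ± 0.36, adjusted p = 0.406) and Nppb (-0.60 ± 0.35, adjusted p = 0.228). The calcium pump Atp2a2 (-0.60 ± 0.49), its inhibitor Pln (-0.69 ± 0.43) and the atrophy ligases Trim63 (-0.35 ± 0.41) and Fbxo32 (0.11 ± 0.30) did not pass either. Trim63 was higher by 0.48 without tumour 1, 2 and trained 2, and by 0.46 with GC correction in addition. Tumour 3 is the only tumour library in both fits. In the first of them Ankrd1, Col1a1, Col3a1 and Gdf15 turned from higher to lower (-1.20, -0.70, -0.92 and -2.17). Trained 2 is in neither group of this comparison. The signs of these genes with only tumour 1 and 2 left out are not given here.

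The count of 868 was not stable, and leaving out a library also changed which genes passed the filter and the common dispersion. It was 182 (113 higher, 69 lower) without tumour 1 and 2, of which 63 were among the 868 in the same direction, and 2463 (1816 higher, 647 lower) with DESeq2. It was 24, 4 and 4 without control 1, 2 and 3, and 6, 8 and 6 without trained 1, 2 and 3. It was 199, 6 and 7043 without tumour 1, 2 and 3, and 7, 9 and 7 without tumour trained 1, 2 and 3. Hmox1, Mt2, Fkbp5 and Serpina3n were the 4 genes called in each of the 12 fits without 1 library and without tumour 1 and 2. Their log2 changes without tumour 1 and 2 were 4.04 (adjusted p = 1.39e-07), 3.97 (1.58e-06), 2.36 (3.43e-04) and 3.29 (2.17e-06). The highest adjusted p over 26 alternatives was 0.0435 for Hmox1, 0.00415 for Mt2, 0.0435 for Fkbp5 and 0.223 for Serpina3n. Lcn2 was called in 23 of the 26, Mt1 in 16 and Angptl4 in 13. In the fit without tumour 1 and 2, which rests on tumour 3 alone and assumes that it varies like the other groups, 5 lists were higher with an estimated correlation too. These were the melanocyte list (0 of 7 genes higher over all genes, 3 adjusted over the list alone; median log2 0.77, adjusted p = 0.0348 with an estimated correlation), oxidative stress (5 of 28 genes higher over all genes, 13 adjusted over the list alone), muscle atrophy and ubiquitin ligases (7 of 31; 13 adjusted over the list alone), glucocorticoid response (10 of 24; 11 adjusted over the list alone) and fatty acid uptake and oxidation (8 of 40; 15 adjusted over the list alone). For the last 4 the adjusted p with an estimated correlation was 0.00176, 0.00162, 0.0112 and 0.0355. With all 12 libraries the atrophy and fatty acid lists did not pass (adjusted p = 0.138 and 0.0674), and the fatty acid list had a negative median of -0.39.

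**Figure D2:**
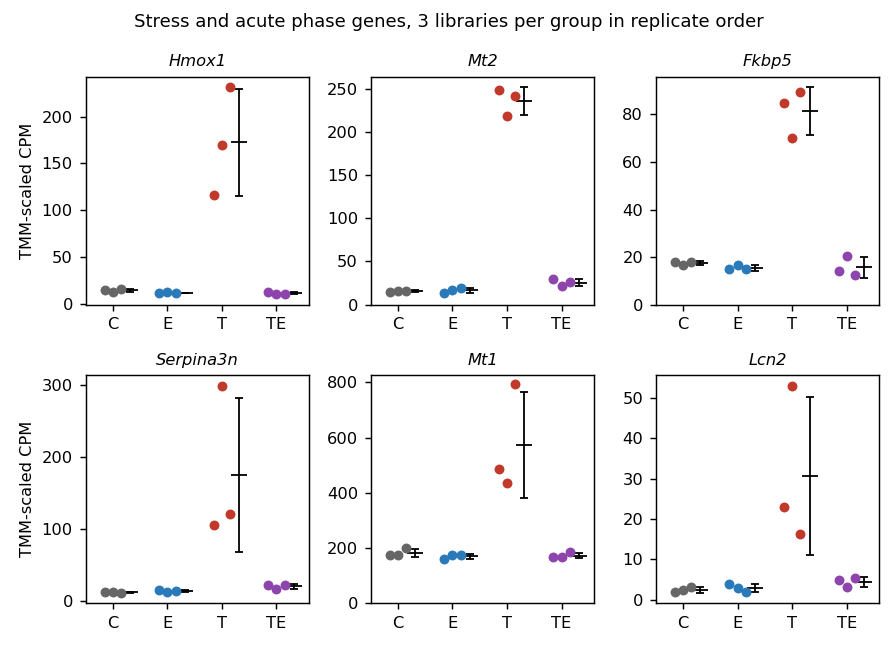
Levels of 6 stress and acute phase genes (vertical axes, TMM-scaled CPM, each starting at 0) in control (C), trained (E), tumour (T) and tumour trained (TE) hearts. Points are libraries 1 to 3 from left to right and bars are the mean ± SD (n = 3). Hmox1 is at 116 to 231 CPM in the tumour libraries and at most 15.6 CPM in the other 9.

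Training in tumour-bearing mice went with lower levels of the same stress genes, close to those of control hearts for Hmox1, Fkbp5 and Mt1. Mt2 was higher in every tumour trained library than in any control (21.3 to 29.1 against 14.5 to 16.1 CPM). So was Serpina3n (17.0 to 23.2 against 12.2 to 12.8 CPM), and Lcn2 was at 3.02 to 5.26 against 1.82 to 3.15 CPM. Tumour trained against control was not tested. Hmox1 fell from 172 ± 57.5 CPM in tumour to 11.3 ± 1.20 CPM in tumour trained hearts (SD, n = 3; log2 -3.93 ± 0.24 SE, adjusted p = 1.55e-05), against 14.1 ± 1.45 CPM in control hearts. Mt2 fell from 236 ± 15.8 to 25.5 ± 3.99 CPM (log2 -3.21 ± 0.18, adjusted p = 9.69e-06) and Fkbp5 from 81.6 ± 10.1 to 15.6 ± 4.31 CPM (log2 -2.38 ± 0.19, adjusted p = 2.48e-04). Serpina3n fell to 20.8 ± 3.28 CPM (adjusted p = 0.00566), Lcn2 to 4.38 ± 1.19 CPM (adjusted p = 0.0357), Mt1 to 172 ± 10.2 CPM (adjusted p = 0.0127) and Angptl4 to 13.8 ± 5.12 CPM (adjusted p = 0.0357). Cdkn1a, a cell cycle inhibitor induced by stress, fell from 172 ± 35.4 to 28.2 ± 12.2 CPM (log2 -2.61 ± 0.39, adjusted p = 0.0357). Of the 31 tested panel genes 8 were lower and 23 did not pass.

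The oxidative stress list had 10 of 28 members lower (12 adjusted over the list alone; adjusted p = 9.58e-06; adjusted p = 0.685 with an estimated correlation). The glucocorticoid response list had 6 of 24 lower (8 adjusted over the list alone; adjusted p = 3.30e-05; adjusted p = 0.685 with an estimated correlation). The 5 melanoma genes held 5.40e-04% to 8.80e-04% of counts in tumour trained hearts, no more than in the tumour-free groups, and the cell cycle list had 28 of 31 members lower (28 adjusted over the list alone; median log2 -4.37, adjusted p = 2.44e-15; adjusted p = 0.685 with an estimated correlation). The cell cycle median was -0.04 without tumour 1 and 2, with no called gene (adjusted p = 0.789). The matrix and fibrosis list had 11 of 44 members lower (1 higher and 17 lower adjusted over the list alone; median log2 -0.89, adjusted p = 2.73e-05; adjusted p = 0.685 with an estimated correlation), but its median was 0.29 without tumour 1 and 2.

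Genes higher in tumour trained than in tumour hearts included Itgb6 (3.64 ± 2.82 to 19.9 ± 3.28 CPM, log2 2.46 ± 0.51), Myh7b (14.3 ± 9.50 to 73.3 ± 5.98 CPM, log2 2.37 ± 0.39) and the cardiac orphan receptor gene Gpr22 (8.79 ± 1.73 to 44.4 ± 4.73 CPM, log2 2.33 ± 0.33, adjusted p = 0.0292). The clock output gene Dbp (11.03 ± 6.51 to 76.3 ± 37.4 CPM, log2 2.80 ± 0.63), and the clock genes Per3 (11.6 ± 5.61 to 45.6 ± 8.56 CPM) and Nr1d2 (52.3 ± 9.69 to 151 ± 3.57 CPM) were higher too, each with adjusted p = 0.0357. Their log2 changes without tumour 1 and 2 were 2.03, 1.32 and 1.28, against 2.80, 1.98 and 1.53, and did not pass with tumour 3 as the only tumour library (adjusted p = 0.295, 0.145 and 0.230).

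In all, 1156 genes were called (229 higher, 927 lower; 2617 with DESeq2). The count was 93 without tumour 1 and 2, of which 27 were shared. It was 8, 4 and 7 without control 1, 2 and 3; 7, 1242 and 4 without trained 1, 2 and 3. It was 111, 6 and 6619 without tumour 1, 2 and 3, and 3 without any 1 of the tumour trained libraries. Hmox1, Mt2 and Fkbp5 were the 3 genes called in each of these fits. Without tumour 1 and 2 the oxidative stress, atrophy, glucocorticoid and fatty acid lists were lower with an estimated correlation as well (adjusted p = 0.00159, 0.00159, 0.0141 and 0.0380), again against tumour 3 alone. The melanocyte list was lower with them (median log2 -1.24, adjusted p = 0.0218 with an estimated correlation).

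In tumour-free mice, training left no gene past the threshold in the fit of 12 libraries, and the clearest difference was in immediate early genes. The list of 27 such genes, switched on within minutes of a stimulus, had a median log2 change of -1.035 (adjusted p = 3.83e-35; adjusted p = 0.182 with an estimated correlation), with 0 members past the threshold over all genes and 12 lower adjusted over the list alone. The AP-1 subunit gene Fosb was at 24.3 ± 20.4 CPM in control and 1.49 ± 0.489 CPM in trained hearts (log2 -4.02 ± 0.96, adjusted p = 1.00). The stress factor gene Atf3 was at 242 ± 203 and 8.53 ± 4.92 CPM (log2 -4.82 ± 1.20, adjusted p = 1.00). The difference lay in control 2 and 3: Fosb was at 0.862, 33.97 and 38.17 CPM and Atf3 at 8.04, 370 and 348 CPM in control 1, 2 and 3.

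Erythrocyte genes had a higher median in trained hearts (11 genes, median log2 1.00, adjusted p = 6.65e-07; adjusted p = 0.571 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone. Its median was 0.50 without trained 1 and ranged from 0.50 to 1.38 over 26 alternatives. The adult beta globin gene Hbb-bs was at 385 ± 161 CPM in control and 813 ± 377 CPM in trained hearts. Angptl4 was at 10.8 ± 3.73 and 46.7 ± 28.6 CPM (log2 2.11 ± 0.49, adjusted p = 1.00). In all, edgeR called 0 genes, with 278 at an unadjusted p below 0.05, and DESeq2 called 2, both lower. The single call without tumour 1 and 2 was Bhlhe40, a repressor in the clock (86.3 ± 3.03 to 41.4 ± 6.29 CPM, log2 -1.06 ± 0.115, adjusted p = 0.0207). With trained 2 left out as well, 1483 genes were called (1102 higher, 381 lower), and 402 with GC correction in addition. A Spearman rho across genes was taken between transcript GC and the log2 ratio of each library to the control mean. It was 0.146, -0.497 and 0.263 in control 1, 2 and 3 and -0.568, 0.625 and -0.583 in trained 1, 2 and 3. Control libraries are part of that mean, so their values do not compare evenly with the others. With trained 2 left out, both trained values lie below every control value, though near that of control 2. The number of lists called, 11 with all libraries, ranged from 5 without trained 2 to 16 without control 1 when 1 library was left out, and was 18 without tumour 1 and 2.

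In trained mice, the tumour was accompanied by no called gene, and its clearest association was with clock genes. The circadian clock list had a median log2 change of 0.59 (21 genes, adjusted p = 3.18e-09; adjusted p = 0.192 with an estimated correlation), with 0 members past the threshold over all genes, and 6 higher and 2 lower adjusted over the list alone. Per3 was at 17.3 ± 6.67 CPM in trained and 45.6 ± 8.56 CPM in tumour trained hearts (log2 1.40 ± 0.35, adjusted p = 1.00), and the clock repressor gene Ciart at 2.501 ± 1.01 and 8.22 ± 1.96 CPM (log2 1.72 ± 0.38, adjusted p = 1.00). The list was called in 25 of 26 alternatives, with a median of 0.52 to 0.69. Hmox1 was at 11.4 ± 0.457 and 11.3 ± 1.20 CPM, and Mt2 at 16.6 ± 3.03 and 25.5 ± 3.99 CPM (log2 0.62 ± 0.17, adjusted p = 1.00).

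Smooth muscle and pericyte genes had a lower median in tumour trained hearts (14 genes, median log2 -0.24, adjusted p = 1.80e-05; adjusted p = 0.970 with an estimated correlation), with 2 lower adjusted over the list alone and 0 over all genes. The contractile genes Tagln (34.0 ± 1.80 to 17.6 ± 3.95 CPM) and Cnn1 (3.13 ± 1.00 to 0.706 ± 0.317 CPM) had the lowest p. In all, edgeR called 0 genes, with 150 at an unadjusted p below 0.05, and DESeq2 called 3 (2 higher, 1 lower).

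**Figure D3:**
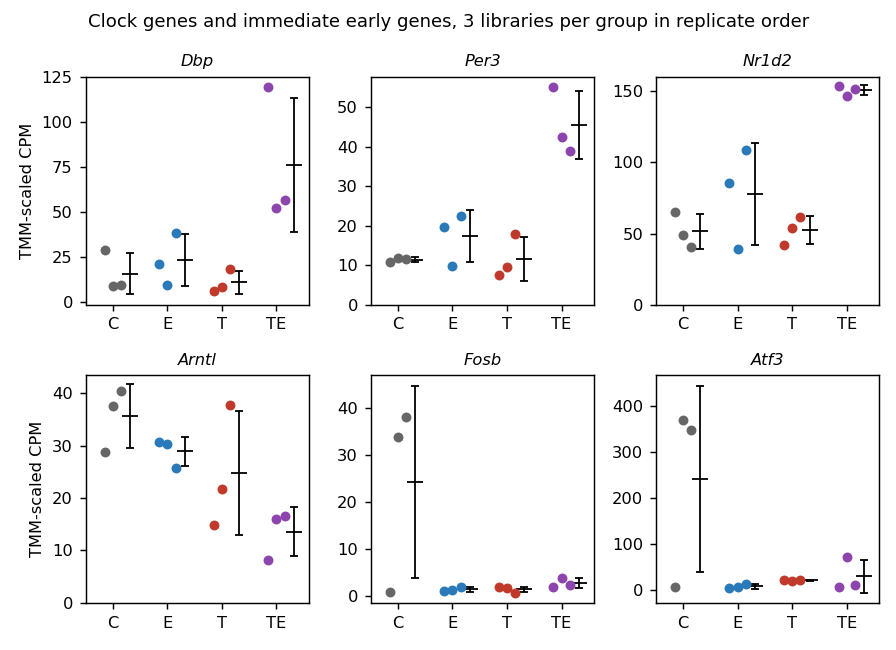
Levels of 4 clock genes and 2 immediate early genes (vertical axes, TMM-scaled CPM, each starting at 0) in control (C), trained (E), tumour (T) and tumour trained (TE) hearts. Points are libraries 1 to 3 from left to right and bars are the mean ± SD (n = 3). Dbp is at 52.4 to 119 CPM in tumour trained hearts.

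The effect of training differed between tumour-bearing and tumour-free mice for 3 genes, Hmox1 (interaction log2 -3.63 ± 0.32, adjusted p = 8.19e-04), Mt2 (-3.31 ± 0.24, adjusted p = 2.05e-04) and Fkbp5 (-2.20 ± 0.27, adjusted p = 0.016). Serpina3n did not pass (-3.31 ± 0.48, adjusted p = 0.0609). Hmox1 was called in 25 of 25 alternatives and Mt2 in 24, whereas Fkbp5 was called in 14, with an adjusted p up to 0.154. DESeq2 called 314 genes. The edgeR count was 3, 2 and 2 without control 1, 2 and 3, and 2, 2 and 3 without trained 1, 2 and 3. It was 6, 4 and 4002 without tumour 1, 2 and 3, and 2, 3 and 2 without tumour trained 1, 2 and 3. The fit without tumour 1 and 2 called 32.

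Of the 868 genes that differed between tumour and control, 596 differed in the opposite direction between tumour trained and tumour hearts, 514 raised then lowered and 82 lowered then raised. Independent lists of these sizes would share 49.4 and 3.35 genes. The log2 changes of the 2 comparisons had r = -0.900 and a covariance of -0.760, with the melanoma transcripts of tumour 1 and 2 among the genes that moved in both. As both use the tumour libraries, 20 simulations without any effect gave r of -0.503 to -0.472, a median covariance of -0.0685 and 0 such genes. The simulations drew each gene independently, with the same spread in every group. They therefore lack the melanoma content that many genes share in tumour 1 and 2, which enters both comparisons with opposite sign. A reversal by training beyond this shared content was not tested. The number of genes that differed in opposite directions was 4 without control 1, 2 or 3, and 4, 7 and 4 without trained 1, 2 and 3. It was 74, 5 and 5630 without tumour 1, 2 and 3, and 3 without any 1 of the tumour trained libraries. Without tumour 1 and 2 it was 76 (61 and 15), with r = -0.684 and a covariance of -0.215, where tumour 3 alone carries both comparisons and no simulation was run. The tumour effects in untrained and trained mice, which share no library, had r = 0.095 (simulated -0.028 to 0.032). The simulated range lacks trends that many genes of a library share, such as that with GC content. It therefore cannot tell whether 0.095 is a shared tumour effect. With 0 genes called for the tumour in trained mice, there could only be 0 shared calls.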

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

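The tests of scaling, of GC content and of library depth were written before their results; all others in this part were chosen after the result was seen.

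Training and tumour combined differently for 3 genes, by an interaction log2 of -3.6267 for Hmox1, -3.3128 for Mt2 and -2.203 for Fkbp5. Lists with a difference between groups, given as the median interaction log2, were sarcomere 0.6823, calcium handling 0.6851, adrenergic signalling 0.32392, potassium and sodium channels 0.75553, oxidative phosphorylation 0.60661, TCA cycle 0.61538 and ketone and branched-chain amino acid metabolism 0.63132. Further lists were glucocorticoid response -0.29522, oxidative stress response -0.05, extracellular matrix and fibrosis -0.64788, circadian clock 0.49648, cell cycle -4.5115, immediate early genes 1.2522, cytosolic ribosomal proteins -0.39275 and growth signalling 0.11919. Cell type lists were cardiomyocytes 0.70919, endothelial cells 0.57671 and melanocytes and B16 melanoma -7.7673. With all 12 libraries none of these list differences held with an estimated correlation; without tumour 1 and 2, glucocorticoid response (-0.730, adjusted p = 0.0286) and oxidative stress response (-0.223, adjusted p = 0.00525) did. In that fit the interaction median was -0.109 for oxidative phosphorylation, -0.043 for the TCA cycle, 0.015 for ketone metabolism, 0.32 for the matrix list, -0.082 for cardiomyocytes, -0.074 for endothelial cells and -0.130 for cell cycle. It was -0.007 for sarcomere, 0.157 for calcium handling, -0.052 for adrenergic signalling, 0.007 for potassium and sodium channels, -0.064 for ribosomal proteins, 0.404 for circadian clock, 0.813 for immediate early genes, 0.081 for growth signalling and -0.957 for the melanocyte list. Mlana, a melanoma gene removed by the filter on low counts, was at 375.13 CPM in tumour 1 and 129.4 CPM in tumour 2 without TMM scaling, with at most 5 counts in any other library.

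Cardiomyocyte genes were low in tumour 1 and 2, where melanoma transcripts were high. Of 18 such genes, 17 stood in the order tumour 1, 2, 3, the reverse of melanoma content, an order already seen in the share of the list that both dilution by melanoma RNA and a heart response graded with tumour load would give. Endothelial genes had a mean log2 ratio to control of -1.1626 in tumour 1 and 2. Melanoma RNA would dilute every heart cell type, so this cannot tell whether cardiomyocytes were a lower share of heart cells. Medians in tumour 1 and 2 were -2.32 and -0.879 for cardiomyocyte genes, and -1.82 and -0.509 for endothelial genes. They were -1.59 and -0.313 for smooth muscle and pericyte genes, so cardiomyocyte genes fell most of these lists. In tumour 3 the cardiomyocyte median was -0.0619, just below the controls (-0.0585 to 0.0343), and 1 library leaves a change of heart transcription open. Whether melanoma cells grew in these hearts or were carried over at dissection was not tested.

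Hmox1, Mt2 and Fkbp5 were high in every tumour library. In tumour trained hearts Hmox1 and Fkbp5 were near control, and Mt2 was lower than in tumour hearts but above every control library (21.3 to 29.1 against 14.5 to 16.1 CPM). Melanoma RNA cannot account for tumour 3, which has almost none and where the lowest of the 3 ratios to control was 5.10. Whether melanoma RNA adds to the levels in tumour 1 and 2 cannot be told. The median ratio of tumour 1 to tumour 3 was 0.949 although cardiomyocyte genes were diluted, but the 3 genes differed. The ratio was 0.503 for Hmox1, 1.03 for Mt2 and 0.949 for Fkbp5. Scaling does not account for the high levels in tumour hearts, as the lowest log2 change over 4 scalings was 2.17. A systemic response to tumour burden that was absent or weaker in trained mice remains a hypothesis, as burden was not measured and melanoma transcripts in trained tumour hearts were no higher than in tumour-free hearts.

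Trained 2 stood apart from trained 1 and 3 in the Spearman rho between transcript GC and the log2 ratio to the control mean. It was 0.625 there, against -0.568 and -0.583. The rho also differed between groups: 0.146, -0.497 and 0.263 in control, -0.284, -0.149 and -0.119 in tumour, and -0.572, -0.615 and -0.679 in tumour trained libraries. Tumour trained and tumour libraries do not overlap in this trend, whereas control and trained libraries do. Control libraries are part of the mean used, so their values do not compare evenly with the others. Removing the GC trend left a variance ratio of 3.37, from 8.32, and 59.7% of the variance lay on this trend. The trend with the median GC of a gene's transcripts is therefore not the whole cause. It may miss part of a GC effect, so GC as the whole cause is not excluded. Thinned to the depth of trained 1, its rho was still 0.611. No biological explanation was tested.

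With 3 libraries per group the 10 possible splits are too few to test the counts of genes: the real grouping gave 868, 1156, 0 and 0 genes in the 4 pairwise comparisons, with 1, 1, 10 and 10 of 10 splits giving as many, and the highest other value was 0. For the interaction, 1 of 60 splits, the real one, gave 3 genes and the highest other gave 0. Moving libraries between groups also scatters the melanoma-rich tumour libraries and breaks up the separate effects of tumour and training. The other splits therefore do not show what would be called without an interaction, and they cannot tell whether the 3 genes arose by chance.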

How the results depend on the processing

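The fits without tumour 1 and 2, without these and trained 2, with GC correction and with scaling to cardiomyocyte genes were chosen after the data were seen; the others were set beforehand. Hmox1 and Mt2 kept direction and call in tumour against control and in tumour trained against tumour in 26 of 26 alternatives. The common dispersion of the fit over all groups was 0.0772 with 12 libraries and 0.0197 without tumour 1 and 2. Of 105 called named genes, 105 kept their call with DESeq2, 100 with its size factors in edgeR, 102 with GC correction, 103 without a filter, 105 with a stricter filter, 93 with robust dispersion and 5 of 97 with only 2 groups fitted. Leaving out 1 library kept from 10 (without control 2, tumour trained 1 or tumour trained 3) to 105 (without tumour 3), and leaving out tumour 1 and 2 kept 28 of 103. Of 77 list calls, 0 held with an estimated correlation. Depth limits genes near 3 counts, 0.225 to 0.339 CPM. Where a value below moved, the cause was not tested. Leaving out 1 library also changed which genes passed the filter on low counts, and the common dispersion. Without control 1, for instance, 13291 genes were tested at a dispersion of 0.0956, and without tumour 3 13289 genes at 0.0415. With 12 libraries these were 12778 genes and 0.0772.

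Counts of genes are given for tumour against control, then tumour trained against tumour, unless named. With a minimum absolute log2 change of 1 they were 723 (596 higher, 127 lower) and 865 (161 and 704), with 0, 0 and 3 in the other comparisons. With library size alone the first was 1971 (1716 higher, 255 lower), with 5 genes in the interaction and 1099 changed back. With only 2 groups fitted they were 3 and 2, with 2 changed back and 16 lists for tumour in trained mice. With DESeq2 they were 2463 and 2617, with 2 genes for training in tumour-free mice, 3 for tumour in trained mice, 314 in the interaction, 1560 changed back and 1 changed by tumour in both. With an estimated correlation the lists were 0, 0, 0, 0 and 0. Without tumour 1 and 2 they were 182 and 93, with 1 for training in tumour-free mice, 32 in the interaction and 76 changed back, and 10 lists for training in tumour-bearing and 18 in tumour-free mice. Without tumour 1, 2 and trained 2, training in tumour-free mice gave 1483 (1102 higher, 381 lower), tumour in trained mice 6, the interaction 133 (47 and 86) and 3 changed by tumour in both, with 11 lists for training in tumour-bearing mice and 22 for tumour in trained mice. With GC correction tumour against control gave 1329 (988 and 341), with 7 lists for training in tumour-free mice and 14 for tumour in trained mice. With GC correction and without trained 2 it gave 15, with 12 changed back, and 4 and 17 lists. With GC correction and without tumour 1, 2 and trained 2, training in tumour-free mice gave 402 (227 and 175), tumour in trained mice 7, the interaction 172 (76 and 96) and 4 changed by tumour in both, with 6 and 21 lists. Scaled to cardiomyocyte genes they were 9193 (9136 and 57) and 7264 (31 and 7233), with 1 in the interaction and 6949 changed back.

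With the replicate number as a block they were 16 (11 and 5) and 18 (4 and 14), with 10 changed back, and 21 of the 105 named genes kept their call. Of 18 pairs with the same number, 3 had r over 0.1 (-0.324 to 0.271), and 3 of 12 libraries correlated best with their own number.

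Leaving out 1 library gave 4 to 7043 genes for tumour against control (lowest without control 2 or 3, highest without tumour 3), 3 to 6619 for tumour trained against tumour, 0 to 1 for training in tumour-free mice, 0 to 0 for tumour in trained mice, 2 to 4002 in the interaction, 3 to 5630 changed back and 0 to 0 changed by tumour in both. Lists ranged 20 to 23, 16 to 21, 5 to 16, 6 to 17 and 17 to 23.

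For genes, direction is the sign of the log2 change. For lists it is the direction of the test against all other genes, and the value printed is the median, which can keep its sign. The median kept its sign for ribosomal proteins (0 after rounding with GC correction) and endothelial cells in tumour against control in each of the 3 fits below that leave out tumour 1 and 2, and for ketone metabolism in the interaction in the first of them. A gene is listed below only if its sign changed and it was called in that comparison with all libraries or in the fit named. A list is given only if it was called with all libraries. Sign changes of genes called in neither fit are left out. A gene listed only once trained 2 was also left out may thus have changed sign with trained 2 kept. Direction reversed without tumour 1 and 2 as follows. Tumour against control: Prkar2b -0.099, Asns -0.944; TCA cycle 0.076, ketone metabolism 0.158, ER stress -0.194, ribosomal proteins 0.011, endothelial cells -0.038. Tumour trained against tumour: Gdf15 0.229, Prkar2b 0.114, Asns 0.435, Rpl3 0.038, adrenergic signalling -0.046, oxidative phosphorylation -0.075, TCA cycle -0.102, ketone metabolism -0.046, ER stress 0.301, matrix 0.288, cardiomyocytes -0.042, endothelial cells -0.251. Interaction: oxidative phosphorylation -0.109, TCA cycle -0.043, ketone metabolism 0.015, matrix 0.32, cardiomyocytes -0.082, endothelial cells -0.074.

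Direction reversed without tumour 1, 2 and trained 2 as follows. Tumour against control: Ankrd1 -1.202, Trim63 0.481, Col1a1 -0.703, Col3a1 -0.917, Gdf15 -2.168, Prkar2b -0.097, Asns -0.944, TCA cycle 0.076, ketone metabolism 0.158, ER stress -0.193, ribosomal proteins 0.011, endothelial cells -0.037. Tumour trained against tumour: Ankrd1 1.612, Trim63 -0.672, Col3a1 0.852, Postn 1.301, Gdf15 0.23, Prkar2b 0.114, Asns 0.435, Rpl3 0.038, adrenergic signalling -0.045, oxidative phosphorylation -0.075, TCA cycle -0.102, ketone metabolism -0.046, ER stress 0.301, matrix 0.288, cardiomyocytes -0.042, endothelial cells -0.251. Interaction: oxidative phosphorylation -0.058, TCA cycle -0.074, ketone metabolism -0.07, matrix 0.385, endothelial cells -0.062.

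Direction reversed with GC correction and without tumour 1, 2 and trained 2 as follows. Tumour against control: Ankrd1 -1.228, Trim63 0.458, Col1a1 -0.686, Col3a1 -0.946, Gdf15 -2.096, Prkar2b -0.133, Asns -0.973, Pdia4 -0.543, Rpl3 -0.019, TCA cycle 0.075, ketone metabolism 0.131, ER stress -0.178, ribosomal proteins 0, endothelial cells -0.038. Tumour trained against tumour: Ankrd1 1.513, Trim63 -0.587, Col3a1 0.88, Gdf15 0.351, Asns 0.428, Rpl3 0.118, oxidative phosphorylation -0.039, TCA cycle -0.121, ketone metabolism -0.084, ER stress 0.293, matrix 0.338, ribosomal proteins 0.029, endothelial cells -0.127. Interaction: oxidative phosphorylation -0.045, TCA cycle -0.064, ketone metabolism -0.052, matrix 0.397, endothelial cells -0.037. Scaling to cardiomyocyte genes moved the median log2 change of all genes from 0.108 to 1.52 in tumour against control and from -0.039 to -1.35 in tumour trained against tumour, so a sign change there shows only a change smaller than this common shift. Under it tumour against control reversed for Trim63 0.477, Ppargc1a 1.159, Apln 0.253 and Vegfa 0.007, and tumour trained against tumour for Trim63 -0.566, Asph -0.264, Pde4d -0.246 and Hlf -0.21.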

Other observations

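The genes in this part were chosen after their values were seen, and none of the values was put to a further test.

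Clock genes Dbp and Nr1d2 were highest in tumour trained hearts. Dbp was at 76.3 ± 37.4 CPM there, against 15.7 ± 11.4 in control, 23.2 ± 14.4 in trained and 11.03 ± 6.51 in tumour hearts (SD, n = 3). Nr1d2 was at 151 ± 3.57 CPM, against 51.4 ± 12.4, 77.8 ± 35.8 and 52.3 ± 9.69. The labels give no hour of dissection.

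Nr4a1, an immediate early gene, was at 17.4, 600 and 553 CPM in control 1, 2 and 3, and at 49.9, 270 and 63.5 CPM in tumour trained 1, 2 and 3. Hbb-bs was at 166, 196 and 718 CPM in tumour 1, 2 and 3, and at 1243, 539 and 657 CPM in trained 1, 2 and 3. Between tumour 3 alone and control, with tumour 1 and 2 left out and tumour 3 assumed to vary like the other groups, Pdk4, a switch from glucose to fat use, had a log2 change of 2.51 (adjusted p = 0.0367), Ucp3 of 1.76 (0.0144) and Bnip3, a mitophagy receptor gene, of 1.40 (0.00161), against 1.54, 0.83 and 0.79 with all 3 tumour libraries.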
